A study of Mus musculus with 8 samples.

How the data were processed

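The series holds 8 samples of primary mouse myoblasts from hindlimb muscle, with 2 libraries in each of 4 groups, namely 5hmC immunoprecipitation and input for the genotypes CTRL and Psat1KO. Per the labels' protocols, genomic DNA was sonicated, immunoprecipitated for 5hmC and made into libraries with a kit for single-stranded and low-input DNA. Per the submitters' processing notes, Trim Galore 0.6.7, Bowtie 1.3.1 and MACS 1.4.2 were used with the mm10 genome build, with no role or order given. The deposited values are a coverage signal per gene in consecutive bins, made by the authors and given as 2 tables, here called set 1 and set 2, with 4 blocks each, for CTRL and Psat1KO and for genes marked UP or DOWN. The tool that made the bins, the window around each gene, the scaling and the rule behind the UP and DOWN marks are not given in the sources used here. Low values were whole multiples of a step that differed between libraries, within 1% of the step for 86.5%, 84.1%, 73.0% and 72.3% of low values (CTRL and Psat1KO of set 1, then of set 2). The inverse of that step gave the depth, on the reading that values are scaled to 1000000 reads. Values were never negative and were taken as not corrected for input, so coverage that an input would show remains in them. The input libraries were not analysed here, so no level of immunoprecipitation over input is reported.

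Each library was assigned by the genotype of its block and the number of its table. The labels do not state that equal numbers pair samples, and with 2 pairs the data cannot settle it. The values show that the tables were not all made alike, so ratios are also given within each set. In set 1 the DOWN genes held no interpolated values between 0 and 0.001, in contrast to the 19.3% of bins in the CTRL library of set 2, so DOWN levels should be set against each other only within a set. Genes were matched to the RefSeq annotation of GRCm38 (the assembly called mm10), 268 by transcript and 5 by symbol, and coordinates are 1-based gene bounds from it.

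The level of a gene was the mean over its bins. The main test, fixed before the data were examined, was limma on log2(signal + 1) with Psat1KO against CTRL, 2 against 2 libraries and no covariate, at an adjusted p under 0.05 (Benjamini-Hochberg). On that scale folds of low signals are strongly understated, and the test is close to one of linear differences. Ratios in figures used a pseudocount of 0.005, and folds in the text are ratios without one. Tested on 20 simulations of this comparison over 273 genes with a replicate spread of 11.5%, the main setting recovered 18.7% of 1.5-fold changes, 53.3% of 2-fold and 81% of 3-fold changes, and called 0.493% of unchanged genes. With the replicate block it recovered 3.33%, 17.7% and 34.3% of these changes. The spread was 1 value for all genes, the median of SDs from 2 libraries each, which tends to lie below the true spread. The shares recovered in the main setting are therefore likely too high. The simulated values held no difference between the sets, so the shares with the block do not describe the block on these data. Groups of genes were tested with camera (preset correlation 0.01 and estimated correlation) and fry where a list had at least 3 members, with Benjamini-Hochberg over the UP and DOWN groups and, separately, over the lists. Camera compares a list with the other tested genes, whereas fry tests the list by itself. Fry's mixed test was added after seeing the data.

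Membership of 16 lists fixed before the data were examined was tested with 10000 random lists matched on gene length in 10 classes, two-sided, against 21900 protein-coding genes, with Benjamini-Hochberg over lists and groups. With 200 random lists of 25 genes, 2% had an unadjusted permutation p under 0.05 among the UP genes, and 0% did among the DOWN genes. Of 50 lists with planted members, 100% did, with 5 members among the UP genes and with 3 or 2 among the DOWN genes, before any adjustment over lists. Random lists hold far fewer such members, so this outcome was nearly fixed and does not show what the adjusted threshold would find. UP and DOWN genes were compared per chromosome with Fisher's exact test.

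The fixed rule named the 6 genes with the largest change in each direction past the threshold and of one direction in both tables, then 2 per list, and always Psat1 and Pax7. As no gene passed, it named only Pax7. The other genes were chosen after their values were seen, by the same ranking without the threshold, and the remaining list members are named to complete each list. Hebp2 was also singled out after its values were seen. Entpd4, Tmem254b and Tmem254c, with signals at or near 0, were not interpreted. Prl2c3 is named by the ranking although its mean lies below 0.005.

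The planned comparison of peak regions, their overlap, their genomic distribution and a binomial test of directions were not run, because the tables hold bins per gene and 1 library per genotype each. Alternatives were other pseudocounts, a replicate block, each replicate left out, autosomes only for directions, no length matching and, chosen after seeing the data, a pseudocount of 0.005, bins limited to 0.5, a filter at a mean signal of 0.005, the median log2 ratio of all genes in a set as 0, autosomes only in limma, scaling to the median signal over genes, that median in place of the mean, the means without Hic1, and the X-linked sum without Capn6 and Pcdh19. The tools were R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.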

Results

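Genomic 5-hydroxymethylcytosine (5hmC), the oxidised form of methylated cytosine made by TET enzymes, was profiled in primary mouse myoblasts grown from hindlimb muscle. The cells carried a floxed Psat1 gene, which encodes an enzyme of serine biosynthesis. CTRL cells had no Cre, and Psat1KO cells carried a Cre allele at Pax7, the transcription factor of muscle stem cells. DNA was immunoprecipitated for 5hmC and sequenced, with 2 immunoprecipitated and 2 input libraries per genotype. The values analysed here cover the 4 immunoprecipitated libraries at 273 genes. The authors marked 220 of these genes UP and 53 DOWN in Psat1KO, and neither the criterion nor the data behind these marks is stated. The UP and DOWN marks were therefore used only as names of gene groups.

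Each gene carried the signal, a read coverage, in consecutive bins, and its level was taken as the mean over the bins. The values came in 2 sets with 1 CTRL and 1 Psat1KO library each, and the number of the set was taken as the replicate number. The smallest step of the values implied 22632699 reads in the CTRL and 30559008 in the Psat1KO library of set 1. In set 2 it implied 69765569 and 69794435. At a mean position of an UP gene this came to 0.539, 0.720, 1.61 and 1.53 reads, in the same order of libraries, so that set 2 gave the less noisy values. The labels do not say whether the replicates came from separate animals. The limma and fry p-values on signal therefore rest only on the spread between these libraries, which may be technical. P-values for list membership and for chromosomes concern which genes were marked and do not use that spread.

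The loci that the genotypes concern come first. Psat1 was not analysed here. Pax7 (chromosome 4, 139737059 to 139833530, minus strand, GRCm38) belonged to the DOWN genes. Its signal was 0.0393 ± 0.010 in CTRL and 0.0368 ± 0.0112 in Psat1KO (SD, n = 2). The Psat1KO value was 0.964 times the CTRL value in set 1 and 0.896 times in set 2. For this and every other DOWN gene the SD also holds the difference between the sets, whose windows seem to differ, and a ratio within a set has no replicate check. The direction at Pax7 turned without CTRL replicate 1 and without Psat1KO replicate 2, where libraries of different sets are compared. Only Psat1KO cells carried the Cre allele at Pax7, so these ratios cannot separate an effect of that allele from one of Psat1 loss. The floxed gene is Psat1, and a level of 5hmC at a locus does not measure whether it was deleted.

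The main comparison asked whether 5hmC at these genes differed between Psat1KO and CTRL myoblasts. Genes with the same direction in both sets were ranked by their mean log2 ratio of Psat1KO to CTRL, with a pseudocount of 0.005. Highest was Capn6, a calpain-family gene of the DOWN group, followed by Pcdh19, a protocadherin gene of cell adhesion in the UP group. The Psat1KO signal of Capn6 was 3.54 times CTRL in set 1 and 1.31 times in set 2. That of Pcdh19 was 1.64 times CTRL over both sets. Dkk2, a secreted modulator of Wnt signalling, and Dcn, the matrix proteoglycan decorin, had lower Psat1KO values in both sets, at 0.718 and 0.771 times CTRL. None of these differences passed the test. limma on log2(signal + 1) called 0 of 273 genes at an adjusted p under 0.05, and 7 genes had an unadjusted p under 0.05, where chance alone gives 13.65. The smallest adjusted p was 1. Because signals near 0.02 are small against a pseudocount of 1, folds below are plain ratios of signal and were not themselves tested.

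Capn6 (chromosome X, 143802236 to 143827412, minus strand) had a signal of 0.00684 ± 0.00410 in CTRL and 0.0133 ± 0.000829 in Psat1KO (SD, n = 2). Capn6 is a DOWN gene, so these means and SDs combine sets whose windows seem to differ. Within a set, the fold was 3.54 in set 1 and 1.31 in set 2. The CTRL signal of Capn6 in set 1, the shallower set, was 0.00394, below the 0.005 of the low-signal filter. The fold of 3.54 is therefore uncertain. Pcdh19 (chromosome X, 133582860 to 133689044, minus strand) had 0.0107 ± 0.00415 in CTRL and 0.0176 ± 0.000926 in Psat1KO, with folds of 2.35 and 1.24. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, had folds of 2.18 and 1.10. The sphingosine-1-phosphate receptor gene S1pr3 had folds of 1.74 and 1.10, and the ribonuclease gene Rnase4 had 1.71 and 1.12. Eva1b (chromosome 4, 126145709 to 126149875, plus strand) was the steadiest of this group, with 0.0141 ± 0.000617 in CTRL and 0.0208 ± 0.00119 in Psat1KO and folds of 1.5 and 1.47. The folds of all 6 genes were smaller in the deeper set 2, for Eva1b only slightly. Without CTRL replicate 1 the difference at Ptgs2 turned its direction. On the log2(signal + 1) scale, leaving out replicates gave 0.0051 to 0.013 for Capn6, 0.0056 to 0.014 for Pcdh19 and 0.0080 to 0.018 for S1pr3, each lowest without CTRL replicate 1. Rnase4 ranged from 0.0045, without Psat1KO replicate 1, to 0.014. The range for Capn6, a DOWN gene, also holds the difference between the sets.

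Among genes with lower Psat1KO values, Dkk2 (chromosome 3, 132085266 to 132180304, plus strand) had 0.0234 ± 0.000139 in CTRL and 0.0168 ± 0.00105 in Psat1KO (SD, n = 2), with folds of 0.753 and 0.683. The mechanosensitive channel gene Piezo2 had folds of 0.628 and 0.768. Mdfi, an inhibitor of myogenic transcription factors, had 0.606 and 0.857, and the forkhead gene Foxs1 had 0.621 and 0.958. The difference at Foxs1 turned its direction without CTRL replicate 1, where that at Mdfi shrank to -0.0083 within a range down to -0.021 (log2(signal + 1) scale). Piezo2 shrank to -0.0047 without Psat1KO replicate 1, within a range down to -0.011. Prl2c3 had folds of 0.523 and 0.637, but its signal stayed at or below 0.00469 in every library, and reads from related prolactin-family genes were not checked for, so the value is uncertain.

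Hic1 (chromosome 11, 75161377 to 75170255, minus strand), a transcriptional repressor expressed in mesenchymal progenitors, had the lowest Psat1KO value relative to CTRL. Its mean signal was 0.218 ± 0.227 in CTRL and 0.0407 ± 0.00445 in Psat1KO (SD, n = 2). A single bin, bin 63, carried 94.4% of the signal of this gene in the CTRL library of set 2. In the other 100 bins the Psat1KO signal was 1.12 times the CTRL signal in set 1 and 1.20 times in set 2. With each bin limited to a signal of 0.5 the direction at Hic1 turned to a higher Psat1KO value. Leaving out CTRL replicate 1 gave the only call of any setting, Hic1 with a limma adjusted p of 0.0135, which rests on this bin.

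**Figure D1:**
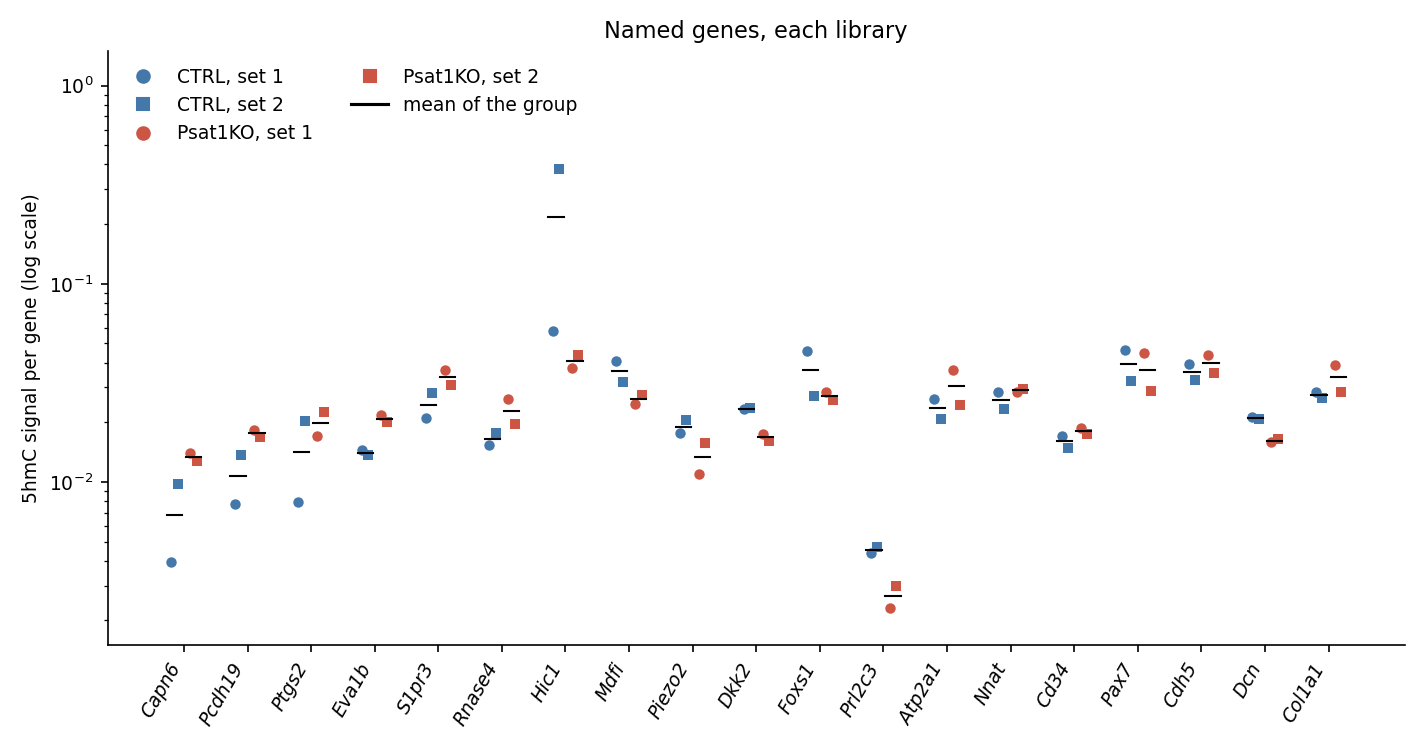
The 5hmC signal of each named gene (log scale, mean over its bins) is plotted for the 2 CTRL and 2 Psat1KO libraries, with circles for set 1, squares for set 2 and black lines for group means. Hic1 in the CTRL library of set 2 stands at 0.378, against 0.0580 in the CTRL library of set 1.

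As a group, the UP genes had nearly the same mean signal in both genotypes. Values seem to be scaled to the reads of each library and were taken as not corrected for input. A 5hmC difference shared by the whole genome would therefore not show in them. The mean signal of the UP genes was 0.0234 ± 0.000570 in CTRL and 0.0228 ± 0.00113 in Psat1KO (SD over libraries, n = 2). Within set 1 the Psat1KO mean differed from CTRL by -1.02%, and within set 2 by -4.52%, which turned to 2.26% without Hic1. The median signal over the UP genes was 3.72% higher in the Psat1KO library of set 1 and 5.50% higher in that of set 2, while the median log2 ratio per gene was -0.05 and 0.04. Per gene, 47.3% of the UP genes were higher and 116 of 220 lower in Psat1KO in set 1, and 132 were higher and 88 lower in set 2. With the median log2 ratio of all genes in a set taken as 0, which was chosen after seeing the data, the count of higher UP genes rose by 1 in set 1 and fell to 112 of 220 in set 2. Higher in both sets were 66 UP genes and lower in both were 50, where independent sets would give 62.4 and 46.4, and the rest had opposite directions. Across UP genes, which are not independent replicates, the log2 ratios of the sets had a Pearson r of 0.152, or 0.0890 without Hic1.

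The DOWN genes had a mean signal of 0.0233 ± 0.00301 in CTRL and 0.0240 ± 0.00327 in Psat1KO (SD over libraries, n = 2). Their Psat1KO mean was 3.58% above CTRL in set 1 and 2.56% above it in set 2. In set 1, 25 DOWN genes were higher, 25 lower and 3 equal, and in set 2, 27 were higher, 24 lower and 2 equal. With the same centring 31 were higher in set 1 and 24 in set 2. Higher in both sets were 14 and lower in both were 13, where independent sets would give 12.7 and 11.3. Limma's fry test for genes moving on balance in a common direction gave an adjusted p of 0.845 for the UP and for the DOWN genes. That fit had no term for the set, so for the DOWN genes its spread also holds the difference between the sets. With the replicate number as a block, a planned setting, fry gave the DOWN genes an adjusted p of 0.111, toward higher Psat1KO signal. It passed for them only with that block and bins limited to 0.5, at an adjusted p of 0.0473 in the same direction. The limit on bins was chosen after seeing the data. Fry's mixed test, for genes changing in either direction, gave an adjusted p of 0.832 for both groups. Among the settings run, it passed only for the UP genes without CTRL replicate 2, with an adjusted p of 0.0372. Limma's camera here only sets the UP against the DOWN genes, with an adjusted p of 0.926, or an adjusted p of 0.964 with an estimated correlation, and does not show whether either group changed. For the UP genes the mean leaned to lower Psat1KO signal, and fry and the median log2 change over genes to higher. A permutation of 2 against 2 libraries cannot give an exact p below 0.333, and with 1 library per genotype no p-value was set on counts of genes within a set. When each library was scaled to its median signal over genes, 85 UP genes in place of 116 and 18 DOWN genes in place of 24 had a higher Psat1KO mean.

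**Figure D2:**
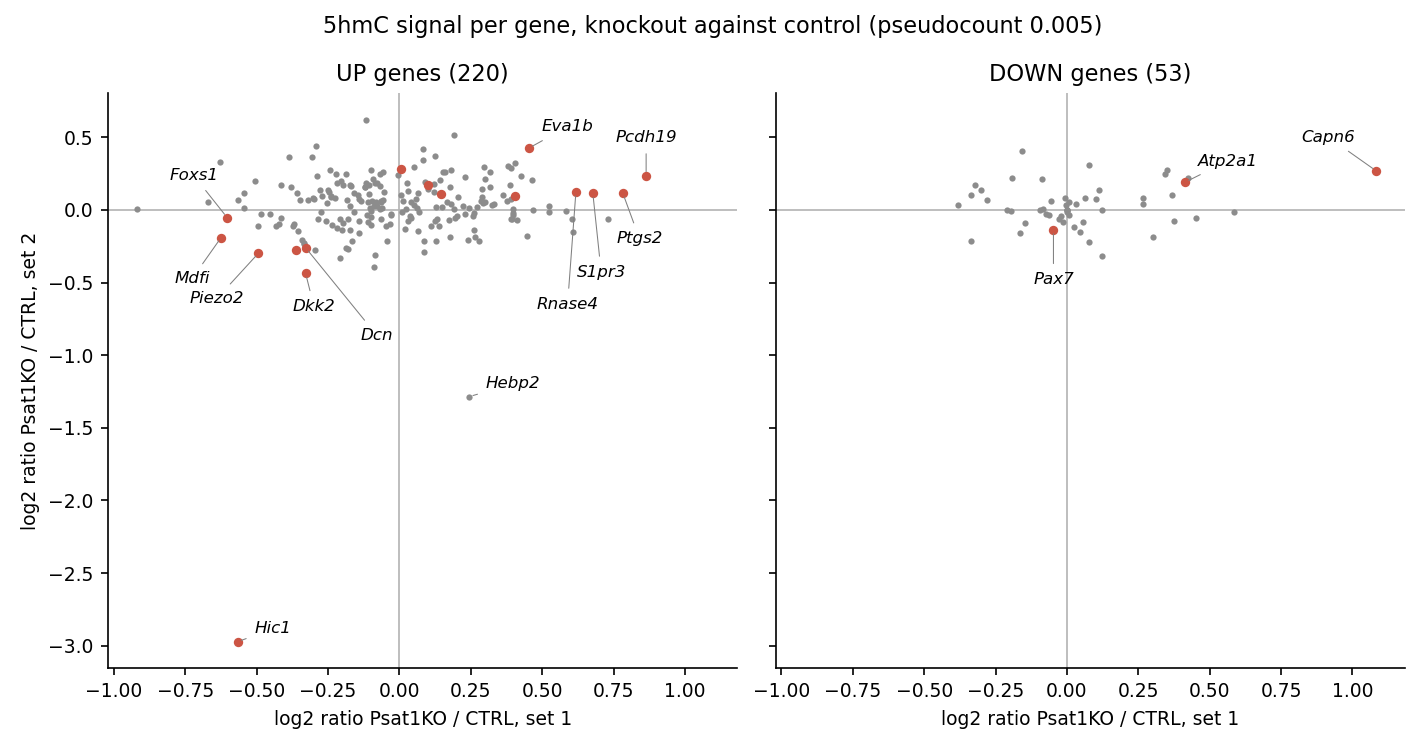
Each point is a gene, placed by its log2 ratio of Psat1KO to CTRL signal (pseudocount 0.005) in set 1 (x axis) and set 2 (y axis), with 220 UP genes on the left, 53 DOWN genes on the right and genes named in the text in red. The UP genes scatter about 0 with a median of -0.05 in set 1 and 0.04 in set 2, and Hic1 and Hebp2 lie far below the rest on the y axis.

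The genes of both groups were then set against 16 gene lists fixed before the data were examined. Markers of fibroadipogenic progenitors, a connective-tissue cell type of muscle, were enriched among the UP genes, with 7 of 17 list members against 0.180 expected. These were the collagen genes Col1a1 and Col1a2, Dcn, the receptor genes Pdgfra and Pdgfrb, and the transcription factor genes Osr1 and Twist2. The permutation adjusted p was 0.00640, from the smallest p that the 10000 random lists can give. Contractile muscle genes were enriched among the DOWN genes, with Atp2a1, Ckm and Myh4 out of 30 against 0.0855 expected (permutation adjusted p = 0.00960). The myogenic factors Myf5 and Myf6 were 2 of 26 commitment genes among the DOWN genes (0.0704 expected, permutation adjusted p = 0.0491). Pax7 and Tenm4 were 2 of 29 quiescence genes there (0.0805 expected), with a permutation adjusted p of 0.0528 that became 0.0448 without matching on gene length. For the commitment and quiescence lists these values lie near the threshold of 0.05, and random lists were drawn without regard to gene position. These enrichments concern which genes the authors marked, not 5hmC, and the choice of genes is not independent of the study. The background was all protein-coding genes and not only those active in the cultured cells. The cells used could alone favour the muscle lists, and the same limit holds for the fibroadipogenic list.

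In 5hmC signal, the fibroadipogenic markers differed in direction. Dcn (chromosome 10, 97479500 to 97518163, plus strand) had 0.0210 ± 0.000383 in CTRL and 0.0162 ± 0.000372 in Psat1KO (SD, n = 2), with folds of 0.749 and 0.794. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) had 0.0274 ± 0.00130 in CTRL and 0.0338 ± 0.00744 in Psat1KO, with folds of 1.38 and 1.08. On the log2(signal + 1) scale its difference of 0.0090 fell to 0.0016 without Psat1KO replicate 1. Col1a2 had folds of 1.32 and 1.04, Pdgfra 1.08 and 1.36, and Twist2 0.780 and 0.945. Pdgfrb, with 1.07 and 0.838, and Osr1, with 0.744 and 1.06, went opposite ways in the sets. None of the 7 members passed the test for single genes over all genes, and 0 passed when adjusted over the list alone. For this list camera, which compares it with the other genes, gave an adjusted p of 0.930, or an adjusted p of 0.963 with an estimated correlation, and fry gave an adjusted p of 0.800. Fry and the median leaned to lower and the mean to higher Psat1KO signal. Fry's mixed test gave an adjusted p of 0.0653, and an adjusted p of 0.274 with the replicate block. With replicates left out its adjusted p lay between 0.0427, without Psat1KO replicate 2, and 0.641, without CTRL replicate 2.

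Among the muscle genes, Atp2a1, the calcium pump of fast fibres, had 0.0236 ± 0.00381 in CTRL and 0.0306 ± 0.00856 in Psat1KO (SD, n = 2), with folds of 1.39 and 1.17. Without Psat1KO replicate 1 its difference on the log2(signal + 1) scale fell from 0.0098 to 0.0014. Creatine kinase Ckm had folds of 0.741 and 1.16, and the fast myosin gene Myh4 had 1.05 and 0.931. Myf5 had 1.02 and 0.899, Myf6 0.955 and 1.06, and Tenm4 0.772 and 1.09. Cd34, a surface marker on the quiescence list and an UP gene, had folds of 1.09 and 1.17. The contractile list had a fry adjusted p of 0.370, and the quiescence list, with Cd34, Pax7 and Tenm4, had an adjusted p of 0.948. In both lists fry leaned to higher Psat1KO signal while the median was lower. The mixed test gave both an adjusted p of 0.815, but with the replicate block it gave the quiescence list an adjusted p of 0.0292 and fry leaned to lower signal. This became an adjusted p of 0.0245 with the block and limited bins, and 0.251 with the block and a pseudocount of 0.005. No member of any fixed list passed the test for single genes, and 0 did when adjusted over the list alone.

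Of the endothelial markers, Cdh5 and Eng were UP genes (permutation adjusted p = 0.175). Cdh5 had folds of 1.12 and 1.09, a direction that turned without Psat1KO replicate 1, and Eng had 0.855 and 1.24. The imprinted gene Nnat had folds of 1.01 and 1.26 and the growth factor gene Fgf2 had 1.75 and 0.948. In the Notch, Wnt and TGF-beta list, Jag1 had folds of 1.39 and 0.947, and Wnt5a had 1.3 and 0.966. Neither group held any member of the lists for TET enzymes and DNA methylation, jumonji demethylases, serine and one-carbon metabolism, glutamine and alpha-ketoglutarate metabolism, the cell cycle, Hox genes, immune cells or neural and glial cells. For these lists only 0.149 to 0.325 UP and 0.03 to 0.115 DOWN members were expected, so their absence is no sign of depletion. By chromosome, UP and DOWN genes did not differ past the threshold on any of 20 chromosomes, and 2 had an unadjusted p under 0.05. Chromosome 4 was closest, with 6 UP and 7 DOWN genes (Fisher's exact test, two-sided, p = 0.00476, adjusted p = 0.0952).

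Along the bins, mean signal over stretches of 20 or more bins lay between 0.0178 and 0.0285 in each group of genes and library, with bins limited to 0.5. In set 2 the UP genes had a Psat1KO signal 3.10% above CTRL in bins 1 to 20 and 6.13% above it in bins 61 to 80. In set 1 the same bins differed by -0.334% and 0.562%. The bins from 81 to the last differed by -3.09% in set 1 and 2.33% in set 2. For the DOWN genes these last bins were 14.6% higher in Psat1KO in set 1 and 7.40% higher in set 2. Their bins 1 to 20 differed by -2.15% and 7.30%, and bins 21 to 40 by -2.94% and -3.05%. The bins of the DOWN genes in set 1 did not correspond to those in set 2, since the median correlation of a gene's profile across sets lay between -0.0202 and -0.00293. These values have no replicate check within a set.

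**Figure D3:**
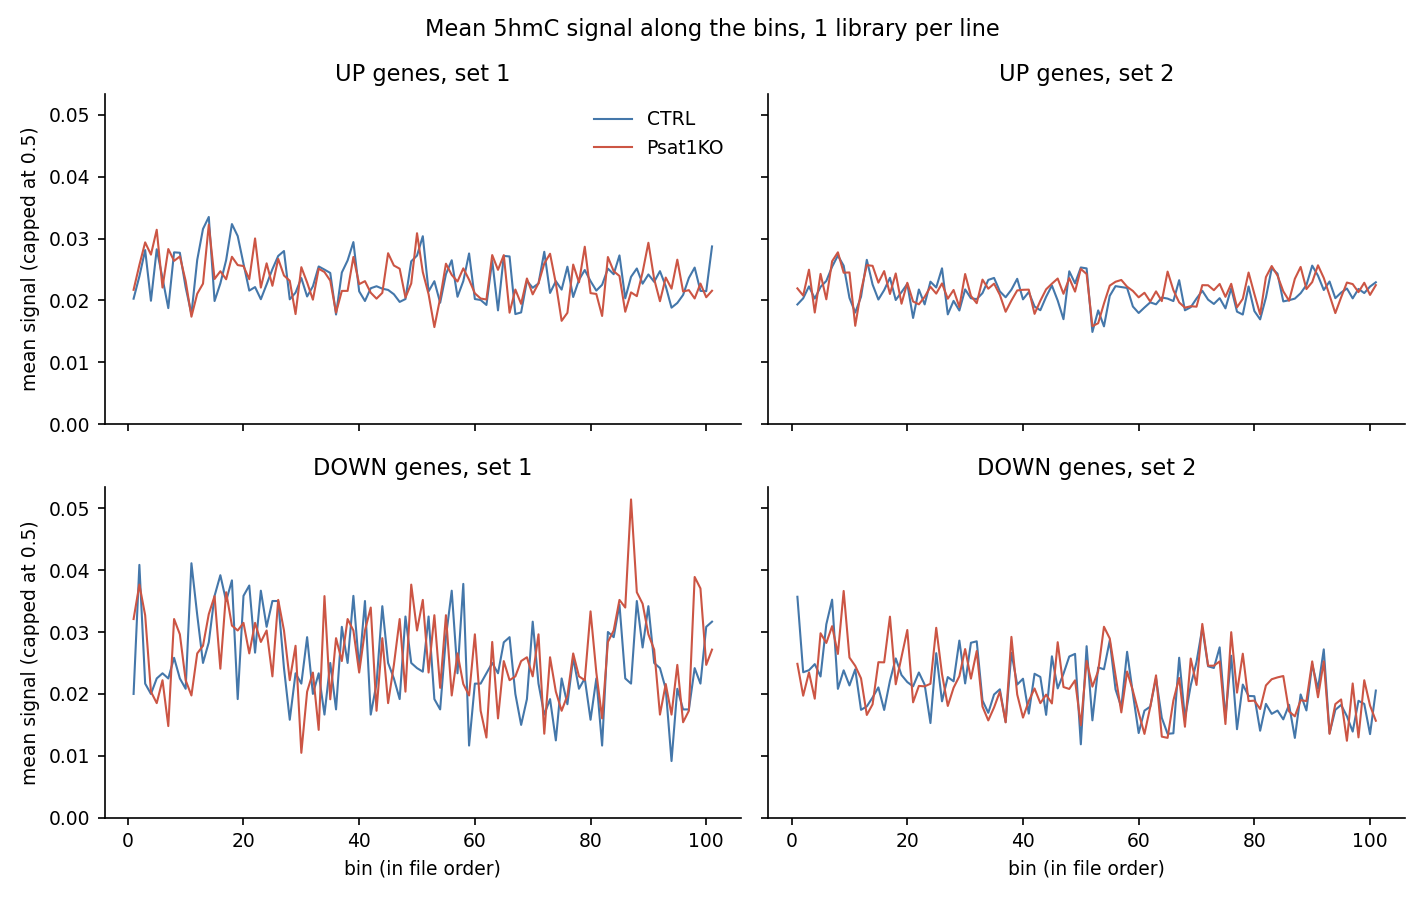
Mean 5hmC signal (y axis, each bin limited to 0.5) is plotted over the bins in the order of the files (x axis) for UP and DOWN genes, with 1 line for the CTRL and 1 for the Psat1KO library of each set. The lines of both genotypes cross many times in every panel, but stay apart over some stretches, such as bins 71 to 83 of the UP genes in set 2.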

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

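Settings chosen only after seeing the data were the pseudocount of 0.005, the limit on bins, the low-signal filter, autosomes only in limma, the median log2 ratio as 0, the median scaling, the median signal, the means without Hic1 and the X-linked sum without Capn6 and Pcdh19. The limma count of called genes was 0 in each setting that kept all libraries, with 4 to 14 genes at an unadjusted p under 0.05. With replicates left out it ranged from 0 to 1, with 0 to 16 genes unadjusted. The 1 call was Hic1 without CTRL replicate 1, where a lone CTRL library is assumed to vary like the others. With the replicate block limma also called 0 genes, with 11 at an unadjusted p under 0.05. The simulation, where it recovered 3.33% of 1.5-fold and 17.7% of 2-fold changes, held no difference between the sets. Those shares therefore do not show what the blocked test could find in these data. The block leaves few degrees of freedom, so this count still says little about stability. Same-numbered libraries deviated together with r = 0.369 over all genes, 0.221 over UP and 0.731 over DOWN genes, but 2 pairs do not settle a pairing. Windows that seem to differ between the sets would shift both libraries of a set together at DOWN genes. The r over DOWN genes, and in part that over all genes, therefore says nothing about paired samples. Fry on the DOWN genes gave an adjusted p of 0.111 with the replicate block, 0.0902 with the block and pseudocount 0.005, and 0.0473 with the block and limited bins, all toward higher Psat1KO signal, within a range over settings from 0.0473 to 0.944. Scaling to the median signal over genes turned fry's direction, with an adjusted p of 0.241 for UP and 0.288 for DOWN genes. Leaving out replicates gave a fry adjusted p between 0.647 and 0.944 for UP and for DOWN genes, with the direction turned without CTRL replicate 2 and without Psat1KO replicate 1. The percent change of mean UP signal turned to 3.72 for the median signal over genes in set 1, and in set 2 to 2.26 without Hic1, 3.08 with limited bins and 5.50 for the median signal. For DOWN genes the median signal gave 8.13 and 1.18, with a median log2 ratio per gene of 0 in both sets. The X-linked sum in set 2 turned from 1.04 to 0.987 times CTRL without Capn6 and Pcdh19. On the log2(signal + 1) scale, Hic1 turned to 0.0052 with limited bins, with or without the replicate block, and ranged from -0.41 to -0.024 with replicates left out. The ranges included 0 for Ptgs2 (-0.00076 to 0.017), Foxs1 (-0.026 to 0.00031), Pax7 (-0.015 to 0.0076) and Cdh5 (-0.00037 to 0.011). They kept their direction but moved over 1.5 times for Col1a1 (0.0016 to 0.016) and Atp2a1 (0.0014 to 0.018), lowest without Psat1KO replicate 1, and for Nnat (0.00094 to 0.0079) and Cd34 (0.0013 to 0.0045), lowest without CTRL replicate 2. The cause was not tested, except that limiting bins acts on single bins by construction. All other direction counts stayed within 1.5 times under the settings run, and lists past the threshold went from 2 to 3 for DOWN genes without length matching. Not run, since the sets hold no regions, authors' p, fold or counts, were the stricter authors' thresholds, overlap and merging settings, promoter and assignment rules, count tests, contigs and gene assignment. At a mean of 0.539 to 1.61 reads per position, depth limits what single genes can show.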

Other observations

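All tests in this part were chosen after the results were seen. The pseudoautosomal gene Erdr1 had high signal in bins 72 to 74 in all 4 libraries, at 1.17 to 1.87, with folds of 0.914 and 1.12 for the whole gene. The UDP-glucuronosyltransferase gene Ugt1a7c had high signal in bin 98, at 0.445 and 0.654 in set 1 and 0.605 and 0.593 in set 2 (CTRL, then Psat1KO), and in bin 99, at 0.306, 0.655, 0.515 and 0.314.

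Bin 63 of Hic1 held 76 and 30 reads in set 1 and 2516 and 128 in set 2 (CTRL, then Psat1KO), while the bins beside it averaged at most 0.0642 in signal. A like pile-up stood in bin 51 of Hebp2, with 14, 5, 309 and 13 reads. A genotype difference in 5hmC across Hic1 would lower its other bins too, but these had Psat1KO signal 1.12 times CTRL in set 1 and 1.20 times in set 2, against a bin 63 that was 3.42 and 19.7 times higher in CTRL. A shared source of reads for both bins stays open: the test of their ratio (permutation of reads, p = 0.436) covers counting error only, and 3 libraries had 5 to 14 reads at Hebp2. A genotype effect on that bin alone stays open too and was not tested.

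Profiles of DOWN genes had a median correlation across sets of at most -0.00293, against 0.219 between the libraries of set 1 and 0.596 between those of set 2. Low depth of set 1 is argued against by the UP genes of the same libraries, whose profiles had a median correlation across sets of at least 0.351. Exchanged gene names are argued against by the mean signal per DOWN gene, whose rank correlation across sets was at least 0.686. These values are consistent with different windows around the DOWN genes in set 1, which may have been made with other settings. No biological explanation was tested, since both genotypes show the pattern.

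The 8 X-linked genes outside the pseudoautosomal region, looked at because Capn6 and Pcdh19 ranked highest, had a summed Psat1KO signal of 1.32 times CTRL in set 1 and 1.04 times in set 2. Without those genes, whose choice raises every value that includes them, the ratios were 1.14 and 0.987. The median log2 ratio of the other 6 genes was 0.295 in set 1, with 4 genes higher, and -0.0715 in set 2, with 2 higher. These medians stood at the 95.3th and the 14.7th percentile of random lists matched on signal, and no bootstrap spread was computed for them. A female against a male library would give a ratio of 2 if signal followed X copies, and the sum of the 8 genes in set 1 lies below that (95% bootstrap interval over genes 1.05 to 1.81), but their median log2 ratio of 0.44 (bootstrap SE over genes 0.30) does not lie 2 SE below 1. A difference in sex, which the labels do not state, and a genotype effect cannot be told apart, because these spreads are over genes and each set has 1 library per genotype.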
